A study of Mus musculus with 10 samples.

How the data were processed

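RNA from epithelial crypts of the mouse distal colon was sequenced in 3 groups, which the labels' treatment field and titles define: control (3 libraries), DSS (4) and AOM+DSS (3). Per the labels' protocols, crypts were released by shaking in EDTA, RNA was isolated with a kit for fibrous tissue, poly(A) RNA was selected, and libraries were made with the TruSeq RNA v2 kit, which does not mark the strand. Per the submitters' processing notes, reads were mapped to the mm9 build of the mouse genome with TopHat2 2.0, and the groups were compared with DESeq. The read counter, the gene annotation, the strand setting of the counting and the DESeq version are not given in the sources used here.

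Values came from 2 tables, each a comparison of a treated group with the control over 23364 genes. Per the file headers, the signal columns are means of normalized read counts (counts divided by a size factor per library) over all libraries and over each group. The authors' fold change is the ratio of the treated mean to the control mean, per the file headers, and their log2 values are its logarithm. The p-values are the authors' DESeq results with a Benjamini-Hochberg adjustment, per the file headers. Genes with both means at 0 have no p-value. The control means are identical in both tables. The header of one table speaks of 4 AOM+DSS replicates, while the labels list 3, and the overall mean in that table equals the plain mean of both group means, as 3 libraries on each side give. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

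The groups, the 30 gene lists, the rule for named genes, the threshold and most of the alternatives were fixed before the data were examined. As the tables hold no counts per sample, the planned count test was not run, and the authors' adjusted p under 0.05 decided which genes were called higher or lower, as planned for tables of this kind. Genes named for a comparison were the 8 with the highest and the 8 with the lowest log2 fold change among those called, with a mean of at least 50 over both groups, both group means above 0, an established symbol, and every recovered treated library on the same side of the control mean. From each list, up to 3 called members with the smallest adjusted p were named, or, where none was called, the 2 with the highest mean. Between the treatments, the 6 highest and 6 lowest differences of log2 fold change were named among genes called in at least 1 comparison, and Actb, Gapdh and Hprt served as a check. Cyp2c65, Des, Lyz1, Reg4, Spp1, Vim and Wif1 fall outside this rule and were chosen after their values were seen, and some genes named for one comparison are also given in the other. A few genes that the rule selects are not reported here, although counts of named genes include them, except in the test for single libraries that stand apart.

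Whole reads per library were recovered from the printed means. A mean of normalized counts is a sum of whole reads, each divided by its library's size factor and by the number of libraries, so the lowest means show a fixed step per library, and a mean printed with enough digits allows 1 combination of whole reads. A value was taken as recovered where exactly 1 combination matched the printed group mean within its rounding. Where several did, it was recovered if only 1 of them also gave the other printed values. This held for 99.9% of genes in control and in AOM+DSS and for 91.0% in DSS. In DSS, genes with a high mean could not be resolved to 1 combination among 4 libraries, and the lowest mean not recovered was 1383. The recovered genes hold 94.0%, 95.3% and 36.9% of the mean total of control, AOM+DSS and DSS. On simulated data, 99.9%, 99.9% and 91.7% of genes were recovered for control, AOM+DSS and DSS, with 0 wrong. Libraries were lettered by depth within their group and cannot be tied to the replicate numbers of the labels, so no pairing was used. Recovered depth ranged from 16165300 to 23593132 reads in control and AOM+DSS; for DSS only the size factors give the full relative depth. The 10 genes with the highest means hold 3.21%, 3.52% and 3.45% of the control, DSS and AOM+DSS totals.

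Limma 3.58.1 (R 4.3.3, trend) was run on log2(normalized recovered reads + 1) for each pair of groups, over genes recovered in both; fold changes from it are differences of mean log values and can lie above or below the logarithm of the ratio of means. It was added after the data were seen, as were the left-out pairs of libraries and the correction for GC content and length, which used GENCODE M21 transcripts (a sequence was found for 92.7% of genes). With 200 genes changed in simulated data, limma found 91% of 2-fold and 100% of 4-fold changes in the DSS comparison, where 7 unchanged genes of 16003 were called. In the AOM+DSS comparison it found 91% and 100%, with 6 unchanged genes of 18309 called, and between the treatments 95% and 99%, with 8 of 16284. In these simulations only well expressed genes were changed, genes varied independently with the typical spread of their expression level, and no library stood apart. The shares found and false calls therefore do not measure how limma performs on the real libraries, some of which stood apart.

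For each gene list, members called higher and lower were compared with all other genes tested by Fisher's exact test (two-sided), with a Benjamini-Hochberg adjustment over 120 tests. Counts adjusted over the list alone use the authors' p-values of the members only. The median log2 fold change was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Camera was run on the limma values with a preset and with an estimated correlation between genes. At the preset, 12 of 29 lists passed in DSS, 13 of 30 in AOM+DSS and 13 of 29 between the treatments, and none of these calls held with an estimated correlation (0 in each, with 4, 5 and 5 lists at an unadjusted p under 0.05). On simulated data, 0 of 30 random lists passed Fisher's test, while a list with planted changes passed in each comparison. Genes were drawn independently there, so this does not measure how Fisher's test performs on lists whose members move together. The lists were Paneth, goblet, tuft, enteroendocrine, absorptive, stem and pan-epithelial cells; Wnt targets and proliferation; 4 inflammatory groups; markers of T and NK, B and plasma, myeloid, endothelial, smooth muscle, fibroblast and squamous cells; and groups for growth factors, regeneration, DNA methylation, histone acetylation, p53, xenobiotics, mitochondria, hypoxia, protein folding and transport. Some genes stand in more than 1 list.

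The overlap of both comparisons was set beside that of independent lists. Both the overlap and the correlation were also set beside 200 simulations of unchanged groups against the same controls, where the overlap used lists as long as the real ones, ranked by change over spread. Ratios for genes with 1 to 3 control reads were taken from pooled recovered reads with an exact 95% interval from the binomial distribution. Libraries of a group were compared by a chi-square test of their reads, by correlation and by principal components of 1000 genes, and no pair was a duplicate. Alternatives were other thresholds, filters and adjustments, other pseudocounts, limma with each library left out, and left-out pairs of libraries. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used elsewhere.

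No coordinates are given, because the tables hold none and the reference used for GC content is of another build. Genes of near-identical families (Defa, Mptx and Khdc1 among those named) are uncertain, since their reads can be split between copies, as are genes that overlap or lie antisense to another. Some list members were absent from the tables under the symbols fixed, mostly because the tables hold an older or newer symbol.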

Results

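Gene expression was measured by sequencing poly(A) RNA from crypts that had been shaken off the mouse distal colon in EDTA, a chelator that loosens the epithelium from the tissue beneath it. The 10 libraries fall into 3 groups. The control group held 3 libraries from untreated mice. The DSS group held 4 libraries from mice given dextran sulfate sodium, which damages the colon lining and inflames it. The AOM+DSS group held 3 libraries from mice given azoxymethane, a carcinogen that alkylates DNA, before DSS, and the submitters describe it as cancer arising from inflammation. The comparisons ask how the epithelial transcriptome differs from control under inflammation and in the resulting cancer.

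The deposited tables give group means, and whole reads per library were recovered from these means. Libraries carry a letter within their group, with a for the deepest, and the letters are not tied to the replicate numbers of the labels. The control libraries a, b and c held 18360378, 18050119 and 16648814 recovered reads, and the AOM+DSS libraries a, b and c held 23593132, 21409134 and 16165300. In DSS, reads were recovered for 21268 of 23364 genes, which hold 36.9% of the group's mean total, so full depth is known only relatively, as size factors of 1.27, 1.21, 0.706 and 0.645 for libraries a to d. The recovered part held 9198433, 8628943, 5029138 and 4654691 reads. No pair of libraries within a group agreed within sampling noise, with chi-square values of 4.57 to 45.2 per degree of freedom.

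Some libraries stood apart from others of their group. Control library b carried more non-epithelial transcripts than the other controls. The recovered fibroblast and extracellular matrix markers summed to 3444 normalized reads, against 730.9 and 760.5. Its 3 recovered MHC class II genes summed to 1076, against 197 and 161. AOM+DSS library c held 14917 normalized reads of smooth muscle markers, against 1849 and 1634 in libraries a and b. DSS library a held 12006 normalized reads of B and plasma cell markers, against 2462 to 3897 in the other DSS libraries. The DSS libraries a and b correlated with c and d at 0.864 to 0.905 (Pearson's r of log2 values across 8819 genes, which are not independent replicates). Libraries c and d correlated at 0.983. Relative to the mean of all libraries, expression followed GC content with Spearman's rho of -0.296 and -0.324 across 8172 genes in DSS libraries a and b and 0.341 and 0.350 in c and d. In AOM+DSS libraries a, b and c it was -0.241, -0.186 and -0.162, and in control 0.186, -0.029 and 0.159. With gene length, rho was 0.342 and 0.262 in DSS libraries a and b and -0.263 and -0.289 in c and d. On the first principal component, with 63.9% of the variance, controls lay at 24.8 to 59.8, DSS at -21.6 to 9.5 and AOM+DSS at -52.1 to -24.7. Of the 3 housekeeping checks, Hprt stood at 2084 ± 129 normalized reads in control (SD, n = 3), 2026 ± 139 in DSS (n = 4) and 2221 ± 218 in AOM+DSS (n = 3). Actb and Gapdh did not pass in either comparison (log2 0.41 and 0.20 in DSS, 0.26 and 0.05 in AOM+DSS) in the authors' deposited table.

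**Figure D1:**
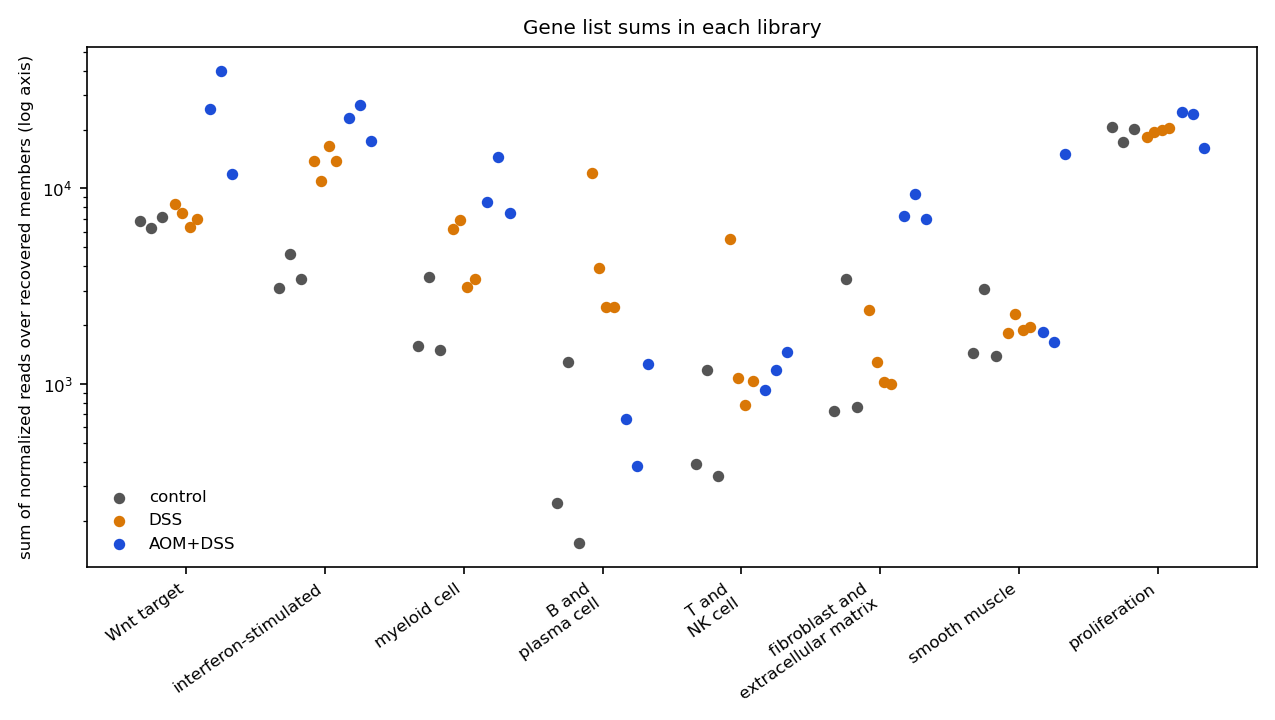
Sum of normalized reads over the recovered members of 8 gene lists in each library (log axis; points are libraries). Smooth muscle markers stand at 14917 in AOM+DSS library c against 1390 to 3053 in all other libraries, and B and plasma cell markers at 12006 in DSS library a.

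The comparison of DSS with control asked which epithelial transcripts differ under inflammation. Higher calls in DSS were made for 8 of 25 cytokines and chemokines, 9 of 20 antimicrobial genes, 16 of 22 interferon-stimulated genes and 7 of 8 MHC class II genes, and lower calls for 5 of 25 xenobiotic-metabolizing enzymes, with 1 higher. These lists passed Fisher's exact test, but none passed camera with an estimated correlation between genes (adjusted p = 0.152 to 0.602). Of 18099 genes tested, 794 passed an adjusted p of 0.05 in the authors' deposited table, 472 higher in DSS and 322 lower. The lowest adjusted p in the authors' deposited table, 1.31e-76, belonged to Slc37a2, a sugar-phosphate exchanger of the endoplasmic reticulum, which fell by 4.28 on the log2 scale. Its recovered level was 9150.0 ± 965 normalized reads in control (SD, n = 3) and 470.3 ± 227 in DSS (n = 4).

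Among called genes with a mean of at least 50 and every recovered DSS library on one side of the control mean, the 8 highest folds belonged to S100a9, Cxcl2, Clec4d, S100a8, Il1b, Cdkn2a, Reg3g and Csf3r. Cxcl2, a chemokine that attracts neutrophils, rose from a mean of 1.95 to 570.3 in the authors' deposited table (log2 8.19). S100a8, a subunit of calprotectin, rose by 7.93 on the log2 scale (adjusted p = 0.0176) and the cytokine Il1b 128-fold (adjusted p = 0.0327) in the authors' deposited table. Reg3g, a secreted antibacterial lectin, rose by 6.08 (adjusted p = 0.00932), and Csf3r, the granulocyte colony-stimulating factor receptor, by 5.62 (adjusted p = 0.0233), again in the authors' deposited table. Across libraries, Reg3g stood at 22.8 ± 25.8 normalized reads in control (SD, n = 3) and 1536 ± 652 in DSS (n = 4). S100a9, the calprotectin partner of S100a8, had 2 pooled control reads and a pooled ratio of 1483 (95% interval 410.2 to 12250). Clec4d, a lectin receptor of myeloid cells, had 1 control read and a ratio of 342 (61.0 to 13520), and Cdkn2a, which encodes INK4A and ARF cell cycle inhibitors, had 3 and a ratio of 103 (34.9 to 499.7). These intervals, here and below, cover counting error only. DSS library b held the highest S100a9, S100a8, Cxcl2 and Clec4d values of its group; S100a9 stood at 2739.6 there and at up to 335.1 in the other 3 libraries.

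The 8 lowest folds under the same conditions belonged to Bex4, Dbp, Foxp2, Slc37a2, Slc30a10, Fxyd4, Rims4 and Pcdh17. Dbp, a circadian transcription factor, fell by 5.51 (adjusted p = 0.00374), and the transcription factor Foxp2 fell by 4.39 (adjusted p = 2.41e-14) on the log2 scale of the authors' deposited table. Foxp2 stood at 190.1 ± 27.1 normalized reads in control (SD, n = 3) and 9.10 ± 1.42 in DSS (n = 4). Slc30a10, a manganese exporter, fell by 4.08 (adjusted p = 0.00771) and Fxyd4, a regulator of the sodium-potassium pump, fell by 3.58 (adjusted p = 4.65e-06), per the authors' deposited table. Log2 changes of -7.75 for Bex4, -3.43 for Rims4 and -3.18 for the protocadherin Pcdh17 passed as well in the authors' deposited table. The DSS mean of Bex4 was only 0.552, so the size of its fold is uncertain. With 10 added to both means it was -3.61.

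**Figure D2:**
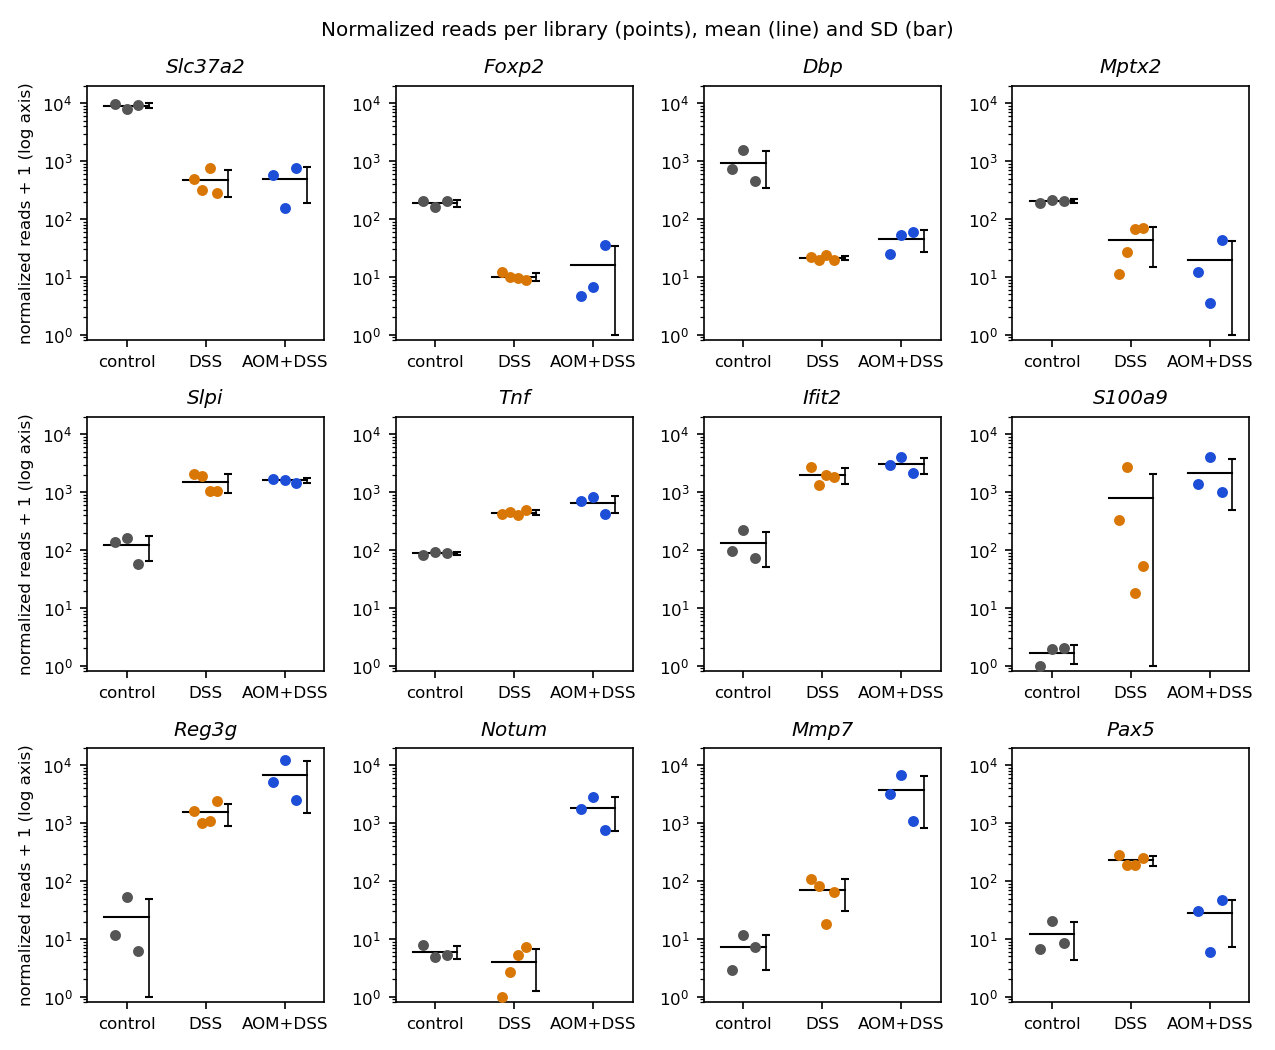
Normalized reads plus 1 per library (log axis) of 12 genes in control, DSS and AOM+DSS; points are libraries, lines group means and bars SD, with lower bars ending at 0 where the SD exceeds the mean. Slc37a2 lies at 8079 to 9952 in control and below 779 in every treated library, and Notum exceeds 750 only in AOM+DSS.

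Of 22 interferon-stimulated genes, 16 rose in DSS and 6 did not pass; 21 rose when adjusted over the list alone. The list held more higher calls than other genes tested (Fisher's exact test, adjusted p = 1.38e-19), while camera gave adjusted p = 0.267 with an estimated correlation. Ifi44 rose by 2.62 (adjusted p = 2.32e-19), Ifit2, which binds viral RNA, by 3.94 (adjusted p = 2.02e-13) and Ifit1 by 1.89 (adjusted p = 2.61e-13) on the log2 scale of the authors' deposited table. Ifit2 averaged 129 ± 78.7 normalized reads in control (SD, n = 3) and 1982 ± 596 in DSS (n = 4).

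Of 8 MHC class II genes, 7 rose and 1 did not pass; all 8 rose when adjusted over the list alone (Fisher's exact test, adjusted p = 1.05e-09; camera on 3 recovered members, adjusted p = 0.420 with an estimated correlation). By the authors' deposited table, Cd74, the invariant chain that guides class II molecules, rose by 2.56 (adjusted p = 2.60e-12), the class II chain H2-Eb1 by 2.70 (adjusted p = 1.36e-10) and the peptide-loading chain H2-DMb1 by 2.28 (adjusted p = 2.07e-13). Markers of B cells and myeloid cells moved with this list: B and plasma cell markers had a median log2 fold of 3.03 in DSS and myeloid markers one of 1.62, against 2.57 for class II. Control library b also held more class II transcripts than the other controls (above).

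Of 20 antimicrobial and acute phase genes, 9 rose, Reg4 fell and 10 did not pass; 12 rose and 2 fell when adjusted over the list alone (Fisher's exact test of higher calls, adjusted p = 8.98e-09; adjusted p = 0.152 with an estimated correlation). Slpi, a secreted inhibitor of leukocyte proteases, rose by 3.66 (adjusted p = 2.43e-15), the inducible nitric oxide synthase Nos2 by 4.26 (adjusted p = 2.24e-09) and Duox2, an epithelial oxidase that makes hydrogen peroxide, by 1.66 (adjusted p = 0.000403) in the authors' deposited table. Slpi averaged 119 ± 56.1 normalized reads in control (SD, n = 3) and 1514 ± 551 in DSS (n = 4). Of 25 cytokines and chemokines, 8 rose and 17 did not pass; 16 rose and 1 fell when adjusted over the list alone (adjusted p = 1.27e-06; adjusted p = 0.296 with an estimated correlation). Tnf rose 5.13-fold (adjusted p = 2.68e-08), the monocyte chemokine Ccl7 20.8-fold (adjusted p = 7.10e-07) and Ccl20, which draws lymphocytes and dendritic cells, by 2.81 on the log2 scale (adjusted p = 1.36e-05) in the authors' deposited table. The Tnf mean was 86.6 ± 5.96 normalized reads in control (SD, n = 3) and 445 ± 41.1 in DSS (n = 4).

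Markers of other cell types moved unequally in DSS. Of 18 myeloid markers, 5 rose and 13 did not pass; 7 rose when adjusted over the list alone (Fisher's exact test, adjusted p = 0.000573; adjusted p = 0.560 with an estimated correlation). Ncf4, a subunit of the phagocyte oxidase, rose by 2.88 (adjusted p = 3.11e-07) and Cd14, a co-receptor for lipopolysaccharide, by 0.91 (adjusted p = 0.00817) in the authors' deposited table. None of 11 B and plasma cell markers passed in the authors' DESeq comparison, although 4 had an unadjusted p under 0.05, 1 rose when adjusted over the list alone and limma called 5 of 10 tested (9 without control library b). Igj, the joining chain of immunoglobulins, stood at a log2 fold of 1.54 (adjusted p = 0.569) in the authors' deposited table. Of 14 T and NK cell markers only Gzmb, a protease of cytotoxic granules, rose, also when adjusted over the list alone (log2 1.46, adjusted p = 0.0488 in the authors' deposited table; limma adjusted p = 0.228). Their median log2 fold was 1.91, above the middle 95% of random lists, matched on mean or not. Camera gave adjusted p = 0.00118 at the preset and 0.662 with an estimated correlation. Recovered T and NK sums were 5536, 1067, 778.8 and 1041 normalized reads in DSS libraries a to d, against 389.1, 1183 and 338.9 in control. Of 16 fibroblast and matrix markers, Pdgfrb, a platelet-derived growth factor receptor, fell, also when adjusted over the list alone (log2 -1.10, adjusted p = 0.00619 in the authors' deposited table), while 15 did not pass. DESeq called 0 of 11 endothelial markers (1 at an unadjusted p under 0.05) and 0 of 10 smooth muscle markers (0 unadjusted), none more when adjusted over the list alone. Limma called 0 in both lists. Vwf stood at a log2 fold of -0.76 and Mylk at 0.43 in the authors' deposited table. The median log2 folds there were -1.67 for fibroblast and -2.04 for smooth muscle markers, both below the middle 95% of random lists. By limma the medians were -0.30 and -1.02 with all libraries, and 1.21 and 0.28 without control library b. Of 9 squamous markers, the keratin Krt13 rose, also when adjusted over the list alone, from a mean of 3.08 to 25.9 (log2 3.07, adjusted p = 0.0218) in the authors' deposited table.

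Few epithelial lineage markers were called in DSS, although the median log2 folds of absorptive colonocyte (0.23), Paneth cell (0.50) and proliferation genes (0.20) lay above the middle 95% of random lists matched on mean. Against random lists not matched on mean, all of these medians lay inside that range. None of 13 pan-epithelial genes passed in DESeq (1 at an unadjusted p under 0.05, 0 when adjusted over the list alone, and 0 by limma on the 1 gene it tested). Krt8 and Krt19 stood at log2 folds of 0.07 and 0.06 in the authors' deposited table. Of 19 absorptive colonocyte genes, the phosphate transporter Slc20a1 fell by 2.40 (adjusted p = 2.62e-18) and Guca2b, which encodes uroguanylin, rose 2.07-fold (adjusted p = 0.0106) in the authors' deposited table. The other 17 did not pass, and 3 rose and 1 fell when adjusted over the list alone (6 higher and 2 lower at an unadjusted p under 0.05). Galnt12, a glycosyltransferase for mucin-type chains, was the one of 16 goblet cell genes that rose, also when adjusted over the list alone (log2 0.65, adjusted p = 0.0491 in the authors' deposited table). Guca2b was also the one of 7 measured Paneth cell genes that rose, with the same count when adjusted over the list alone. Of 14 stem cell genes, Prom1, a membrane protein of stem and progenitor cells, rose by 1.28 (adjusted p = 0.00138) and the water channel Aqp1 fell by 1.12 (adjusted p = 2.89e-05) in the authors' deposited table; 1 rose and 3 fell when adjusted over the list alone. DESeq called 0 of 15 enteroendocrine genes (2 at an unadjusted p under 0.05; limma 1), 0 of 11 tuft cell genes (0 unadjusted; limma 0), 0 of 22 Wnt targets (3 unadjusted; limma 3 of 20 tested) and 0 of 24 proliferation genes (3 unadjusted; limma 2 of 22 tested, and 0 without control library b), and none of these when adjusted over the list alone. Examples from the authors' deposited table are log2 folds of 0.13 for the granule protein Chgb, 0.02 for the tuft cell channel Trpm5, 0.40 for Ccnd1 (cyclin D) and 0.19 for Mki67, a marker of cycling cells.

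Of 17 genes of fetal and regenerating epithelium, 7 rose and 10 did not pass; 8 rose and 1 fell when adjusted over the list alone (Fisher's exact test, adjusted p = 1.12e-06; adjusted p = 0.602 with an estimated correlation). The authors' deposited table has Msln (mesothelin) higher by 3.04 (adjusted p = 1.63e-07), the surface protein Ly6e by 0.88 (adjusted p = 0.000729) and the secreted chaperone Clu by 1.60 (adjusted p = 0.0121) on the log2 scale. Of 18 tumour-associated growth factors and proteases, the EGF receptor ligands Areg (log2 2.17, adjusted p = 0.000241) and Hbegf (log2 1.43, adjusted p = 1.36e-05) rose in the authors' deposited table; 5 rose and 1 fell when adjusted over the list alone (Fisher's exact test, adjusted p = 0.394).

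Of 25 genes of xenobiotic metabolism, 5 fell, 1 rose and 19 did not pass; 6 fell and 1 rose when adjusted over the list alone (Fisher's exact test of lower calls, adjusted p = 0.000548; adjusted p = 0.602 with an estimated correlation). The glucuronosyltransferase Ugt2b35 fell by 1.19 (adjusted p = 6.71e-05), the sulfotransferase Sult1a1 fell by 1.13 (adjusted p = 0.000514) and the glutathione transferase Gstm1 fell by 0.90 (adjusted p = 0.000233), while the cytochrome Cyp2c65 rose by 1.36 (adjusted p = 0.0140), all in the authors' deposited table. Of 21 genes of mitochondrial respiration and butyrate oxidation, the coactivator Ppargc1a fell, also when adjusted over the list alone (log2 -0.81, adjusted p = 0.0197 in the authors' deposited table). Of 16 genes of hypoxia and glycolysis, hexokinase Hk2 rose (log2 1.03, adjusted p = 0.0124) and Bnip3, a mitophagy receptor, fell (log2 -0.94, adjusted p = 0.00697) in the authors' deposited table; 2 rose and 2 fell when adjusted over the list alone. Of 14 genes of histone acetylation, the deacetylases Hdac11 (log2 -1.14, adjusted p = 6.83e-06) and Hdac5 (log2 -0.80, adjusted p = 0.00516) fell in the authors' deposited table, the same count when adjusted over the list alone (Fisher's exact test, adjusted p = 0.157). Of 16 p53 targets, Rprm (log2 -2.40, adjusted p = 0.00443), which arrests the cell cycle, and the cytokine Gdf15 (log2 -1.28, adjusted p = 0.00591) fell in the authors' deposited table, likewise 2 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.193). DESeq called 0 of 21 DNA methylation and Polycomb genes (1 at an unadjusted p under 0.05), 0 of 16 genes of the unfolded protein response (2 unadjusted) and 0 of 21 bile acid, water and ion transport genes (5 unadjusted). Limma called 0 of the 21, 7 and 11 members it tested, and the counts were 0 when adjusted over the list alone. Among them the DNA methyltransferase Dnmt1 stood at a log2 fold of -0.17 and the anion exchanger Slc26a3 at -0.53 in the authors' deposited table.

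Limma on the recovered reads called 876 of 16003 genes, but 147 without control library a, 150 without control library c and 501 without DSS library d. It called 34 of the 40 named and called genes with recovered DSS reads, and those it did not call include Clec4d, Csf3r, Gzmb, Il1b and Krt13. Of the 34, 15 lost the call without control library a, 17 without control library c and up to 3 without any other.

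The comparison of AOM+DSS with control asked which transcripts differ in the cancer that follows carcinogen and inflammation. Higher calls were made for 10 of 22 Wnt targets, 4 of 9 Paneth cell genes, 11 of 18 tumour-associated growth factors and proteases, 13 of 18 genes of fetal and regenerating epithelium and most members of 4 inflammatory lists. Of 25 xenobiotic-metabolizing enzymes, 9 were called lower and 1 higher. These lists passed Fisher's exact test, but none passed camera with an estimated correlation (adjusted p = 0.267 to 0.602). The authors' deposited table calls 1630 of 18334 genes at an adjusted p of 0.05, 1016 higher in AOM+DSS and 614 lower. Notum, a secreted enzyme that inactivates Wnt proteins, rose from a mean of 4.98 to 1812 in the authors' deposited table (log2 8.51, adjusted p = 9.57e-05). Its 3 AOM+DSS libraries held 1812 ± 1073 normalized reads (SD, n = 3) against 4.98 ± 1.55 in control (n = 3).

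Among called genes with a mean of at least 50, the 8 highest folds included those of S100a9, S100a8, Clec4d, Clec4e, Dkk2, Mmp7 and Cxcl2. Mmp7 (matrilysin), a protease that also processes defensins, rose by 9.18 (adjusted p = 0.00295) and S100a8 by 10.15 (adjusted p = 0.00172) on the log2 scale of the authors' deposited table. Cxcl2 passed as well, at an adjusted p of 0.00353 and a mean that rose from 1.95 to 1000.5 in the authors' deposited table. Mmp7 stood at 6.38 ± 4.47 normalized reads in control (SD, n = 3) and 3708 ± 2879 in AOM+DSS (n = 3). From pooled reads, S100a9 had a ratio of 3315 over 2 control reads (95% interval 917 to 27380) and the Wnt antagonist Dkk2 one of 680.4 over 2 (188 to 5623). The myeloid lectin receptors Clec4d and Clec4e, each with 1 control read, had ratios of 837 (149.9 to 33110) and 676 (121 to 26720). The 8 lowest folds belonged to Slc30a10, Dbp, Slc37a2, Rims4, Foxp2, Pcdh17, Mptx2 and Mptx1. In the authors' deposited table Slc37a2 fell by 4.20 (adjusted p = 1.95e-61), Slc30a10 fell by 4.64 (adjusted p = 0.00361), Dbp fell by 4.37 (adjusted p = 0.0353) and Foxp2 fell by 3.67 (adjusted p = 1.89e-10) on the log2 scale. The related mucosal pentraxins Mptx1 and Mptx2 fell by 3.23 (adjusted p = 5.11e-07) and fell by 3.42 (adjusted p = 3.23e-11) in the authors' deposited table. Mptx1 ranged widely within AOM+DSS, from 160.5 to 12459 normalized reads, with the highest value in library c.

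Of 22 Wnt targets, 10 rose and 12 did not pass; 14 rose when adjusted over the list alone (Fisher's exact test, adjusted p = 9.17e-07; adjusted p = 0.493 with an estimated correlation). Besides Notum, Dkk2 and Mmp7, the glycoprotein Dkk3 rose by 3.99 (adjusted p = 1.11e-05), the adhesion receptor Cd44 by 2.23 (adjusted p = 5.50e-05), the secreted Wnt inhibitor Wif1 by 6.99 (adjusted p = 0.000973) and Ccnd1 by 0.75 (adjusted p = 0.00773) in the authors' deposited table. Recovered Wnt target reads summed to 25562, 40061 and 11804 in AOM+DSS libraries a, b and c, against 6254 to 7120 in control. Without control library b and AOM+DSS library c, limma called 18 of the 22 Wnt targets higher, against 13 with all libraries. Of their groups, control library b lay nearest AOM+DSS and AOM+DSS library c nearest control on the first principal component (24.8 and -24.7). Library c also had the lowest Wnt target sum of AOM+DSS. Leaving both out, chosen after the data were seen, widens the contrast, so counts from this fit, here and below, are no added evidence. Stromal and myeloid markers were also higher in AOM+DSS as a group. Fibroblast and matrix sums were 7258, 9420 and 7017 normalized reads in AOM+DSS libraries a, b and c, against 730.9, 3444 and 760.5 in control. Myeloid markers had a median log2 fold of 3.01. Single libraries followed this only in part. Control library b held the highest fibroblast sum of its group but the lowest Wnt target sum (6254, against 6789 and 7120). Its Paneth cell sum was the highest of its group (1552.5, against 950.0 and 1301.8). AOM+DSS library b was highest in the fibroblast, Wnt target and Paneth cell sums. AOM+DSS libraries a and c had similar fibroblast sums, while their Wnt target sums were 25562 and 11804. Of 9 Paneth cell genes, 4 rose and 5 did not pass; 6 rose when adjusted over the list alone (Fisher's exact test, adjusted p = 0.00666; adjusted p = 0.296 with an estimated correlation). Lyz1 (lysozyme) rose by 6.37 on the log2 scale of the authors' deposited table (adjusted p = 0.0353), and Mmp7, which stands in several lists, rose as above. The defensins Defa17 (mean 99.4, adjusted p = 5.22e-12) and Defa5 (mean 27.8, adjusted p = 0.00268), listed at 0 in control and DSS, rose as well in the authors' deposited table. Defa17 held 120, 106 and 71.8 normalized reads in AOM+DSS libraries a, b and c.

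**Figure D3:**
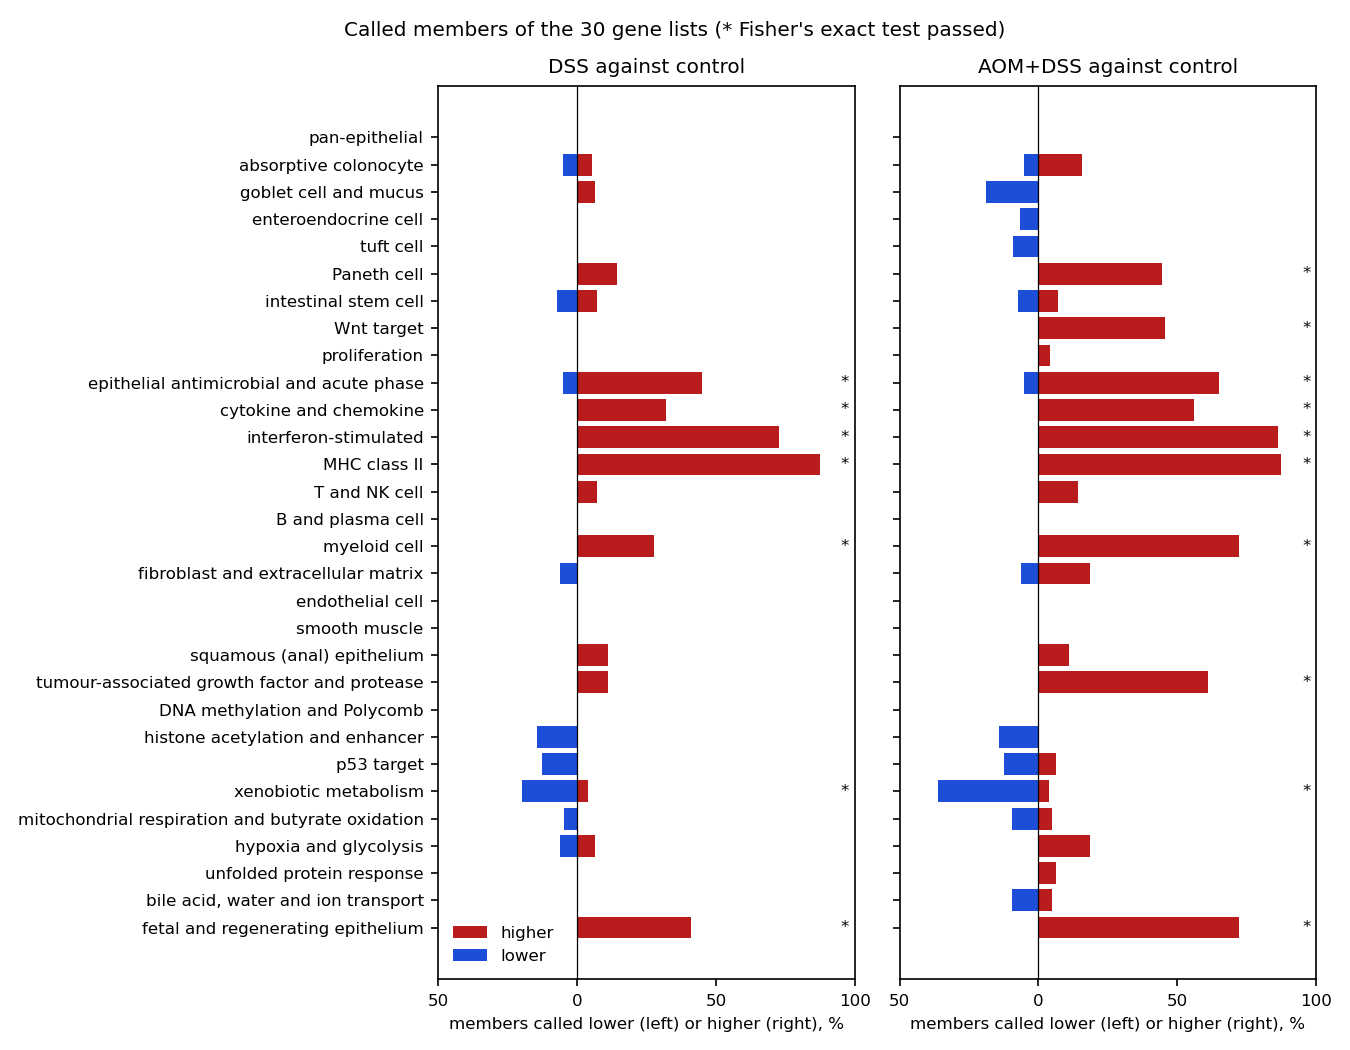
Percent of measured members called higher (right) or lower (left) in each of 30 gene lists, for DSS and AOM+DSS against control; asterisks mark lists that passed Fisher's exact test. In the Wnt target list 0 of 22 members were called in DSS and 10 of 22 in AOM+DSS.

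Of 18 tumour-associated growth factors and proteases, 11 rose and 7 did not pass; 13 rose when adjusted over the list alone (Fisher's exact test, adjusted p = 4.79e-09; adjusted p = 0.390 with an estimated correlation). Ctgf, a matrix-associated growth regulator, rose 13.1-fold (adjusted p = 0.000211), Areg 4.65-fold (adjusted p = 0.000169) and Hbegf 2.38-fold (adjusted p = 0.000282) in the authors' deposited table. Of 18 genes of fetal and regenerating epithelium, 13 rose and 5 did not pass; 15 rose when adjusted over the list alone (Fisher's exact test, adjusted p = 8.56e-12; adjusted p = 0.296 with an estimated correlation). Clu rose by 2.93 (adjusted p = 5.88e-07), Msln by 3.39 (adjusted p = 1.46e-08) and osteopontin, encoded by Spp1, by 8.71 (adjusted p = 6.47e-06) on the log2 scale of the authors' deposited table. Clu averaged 609.7 ± 206 normalized reads in control (SD, n = 3) and 4659 ± 1377 in AOM+DSS (n = 3). The stromal and myeloid markers given for the Wnt targets were higher in AOM+DSS along with both of these lists. Ctgf and several proteases of the list are also made by stromal cells.

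The inflammatory lists were higher in AOM+DSS as well. Of 22 interferon-stimulated genes, 19 rose and 3 did not pass; 20 rose when adjusted over the list alone (Fisher's exact test, adjusted p = 1.38e-19; adjusted p = 0.267 with an estimated correlation). Ifi44 rose 7.68-fold (adjusted p = 6.13e-23), Ifit1 4.89-fold (adjusted p = 4.32e-19) and the guanylate-binding protein Gbp3 7.33-fold (adjusted p = 1.12e-18) in the authors' deposited table. Of 20 antimicrobial genes, 13 rose, Reg4 fell and 6 did not pass; 14 rose and 1 fell when adjusted over the list alone (adjusted p = 5.58e-11; adjusted p = 0.296 with an estimated correlation). Slpi rose 13.5-fold (adjusted p = 9.77e-15), Nos2 37.3-fold (adjusted p = 4.00e-13) and Duox2 4.13-fold (adjusted p = 1.46e-06) in the authors' deposited table. Reg3g stood at 6735 ± 5254 normalized reads in AOM+DSS (SD, n = 3), and the antimicrobial list summed to 20187, 54142 and 12033 normalized reads in libraries a, b and c. Of 25 cytokines and chemokines, 14 rose and 11 did not pass; 16 rose and 1 fell when adjusted over the list alone (adjusted p = 1.19e-10; adjusted p = 0.296 with an estimated correlation). Tnf rose 7.52-fold (adjusted p = 3.44e-12), Ccl7 40.4-fold (adjusted p = 2.33e-10) and Cxcl5, a chemokine for neutrophils, 63.6-fold (adjusted p = 6.04e-05) in the authors' deposited table. Of 8 MHC class II genes, 7 rose and 1 did not pass, the same count when adjusted over the list alone (adjusted p = 1.44e-07; adjusted p = 0.570 with an estimated correlation). Cd74 rose 5.51-fold (adjusted p = 2.74e-11), H2-Eb1 6.38-fold (adjusted p = 4.52e-10) and H2-DMb1 5.17-fold (adjusted p = 4.44e-14) in the authors' deposited table. Control library b held 9632 normalized reads of Cd74, against 1223 and 812 in the other controls and 20297 to 22152 in AOM+DSS.

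Of 18 myeloid markers, 13 rose and 5 did not pass; 17 rose when adjusted over the list alone (Fisher's exact test, adjusted p = 8.56e-12; adjusted p = 0.477 with an estimated correlation). The complement component C1qa rose 8.07-fold (adjusted p = 2.53e-05), Cd14 2.40-fold (adjusted p = 4.79e-05) and Ncf4 4.53-fold (adjusted p = 0.000486) in the authors' deposited table. Of 14 T and NK cell markers, the granzymes Gzmb (log2 2.41, adjusted p = 0.000401) and Gzma (log2 2.23, adjusted p = 0.0422) rose in the authors' deposited table, likewise 2 when adjusted over the list alone. None of 11 B and plasma cell markers passed in DESeq (0 at an unadjusted p under 0.05), in limma with all libraries or adjusted over the list alone, while limma without control library b and AOM+DSS library c called 4 higher. Igj, the joining chain of antibodies, had a log2 fold of 1.68 (adjusted p = 0.564) in the authors' deposited table. Of 16 fibroblast and matrix markers, fibronectin Fn1 (log2 3.77, adjusted p = 0.00548), the matrix protein Fbln1 (log2 3.02, adjusted p = 0.00603) and vimentin Vim (log2 3.52, adjusted p = 0.0411) rose in the authors' deposited table, while Pdgfrb fell (log2 -1.33, adjusted p = 0.000283). The count was 3 higher and 1 lower when adjusted over the list alone (Fisher's exact test of higher calls, adjusted p = 0.302), and limma without control library b and AOM+DSS library c called 11 higher. Neither the 11 endothelial markers (1 at an unadjusted p under 0.05) nor the 10 smooth muscle markers (0 unadjusted) had a call in DESeq, in limma with all libraries or adjusted over the list alone. Without control library b and AOM+DSS library c limma called 4 endothelial markers higher and 2 lower, and 2 smooth muscle markers higher. Tagln, an actin-binding protein of smooth muscle, had a log2 fold of 2.16 (adjusted p = 0.932) in the authors' deposited table, and muscle transcripts were concentrated in library c. Des (desmin) held 2617 normalized reads in AOM+DSS library c, against 5.21 and 5.79 in the other AOM+DSS libraries. Of 9 squamous markers Krt13 rose, also when adjusted over the list alone (log2 4.11, adjusted p = 0.000189 in the authors' deposited table).

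Several differentiated lineages had members that fell. Of 16 goblet cell genes, Clca3, a secreted mucus component (log2 -0.91, adjusted p = 0.0119), the transcription factor Creb3l1 (log2 -0.91, adjusted p = 0.00728) and the protease Capn9 (log2 -0.86, adjusted p = 0.0411) fell in the authors' deposited table, while 13 did not pass. Adjusted over the list alone, 3 goblet genes fell and 1 rose (Fisher's exact test of lower calls, adjusted p = 0.101). The hormone Insl5 was the one of 15 enteroendocrine genes that fell (log2 -1.27, adjusted p = 0.00975), and Rgs13, a regulator of G-protein signalling, the one of 11 tuft cell genes (log2 -1.29, adjusted p = 0.0441), in the authors' deposited table. Adjusted over the list alone, 1 enteroendocrine gene fell, and 3 tuft cell genes fell and 1 rose. Limma called none of Creb3l1 (log2 -0.99, adjusted p = 0.0531), Capn9 (log2 -1.03, adjusted p = 0.107), Insl5 (log2 -1.70, adjusted p = 0.111) and Rgs13 (log2 -1.70, adjusted p = 0.146), although its folds were no smaller, and Clca3 was not tested. The median log2 folds of the goblet, enteroendocrine and tuft cell lists were -0.307, -0.642 and -1.068 in the authors' deposited table. Each lay below the middle 95% of random lists, matched on mean or not. By limma with all libraries these medians were -0.315, -0.737 and -1.381. Camera did not pass these lists even at the preset correlation (adjusted p = 0.403, 0.169 and 0.349). Over these lists limma called 3 goblet, 2 enteroendocrine and 1 tuft cell genes higher and 0 lower with all libraries. Without control library b and AOM+DSS library c it called 2 goblet genes higher and 5 lower, 3 enteroendocrine genes higher and 5 lower, and 1 tuft cell gene higher and 2 lower. None of 13 pan-epithelial genes passed in DESeq (2 at an unadjusted p under 0.05) or adjusted over the list alone, and limma called 0 of 11 tested (2 higher and 2 lower without those 2 libraries), with log2 folds of -0.27 for both Krt8 and Krt19 in the authors' deposited table. Of 19 absorptive colonocyte genes, 3 rose and 1 fell; 3 rose and 3 fell when adjusted over the list alone. Scnn1g, a subunit of the epithelial sodium channel, rose by 2.74 (adjusted p = 0.000614) and Slc20a1 fell by 2.59 (adjusted p = 1.85e-17) in the authors' deposited table. Of 14 stem cell genes, Prom1 rose (log2 1.72, adjusted p = 1.50e-06) and Aqp1 fell (control mean 2.07 times the AOM+DSS mean, adjusted p = 0.000262) in the authors' deposited table, with 4 higher and 2 lower when adjusted over the list alone. Of 24 proliferation genes only Rrm2, a ribonucleotide reductase subunit, rose in DESeq, also when adjusted over the list alone (log2 0.99, adjusted p = 0.0238 in the authors' deposited table). However, 6 rose at an unadjusted p under 0.05. The median log2 fold of 0.23 lay above the middle 95% of random lists matched on mean, but inside that range for lists not matched. Limma called 1 higher with all libraries and 9 without control library b and AOM+DSS library c.

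Of 25 genes of xenobiotic metabolism, 9 fell, 1 rose and 15 did not pass; 10 fell and 1 rose when adjusted over the list alone (Fisher's exact test of lower calls, adjusted p = 6.89e-07; adjusted p = 0.602 with an estimated correlation). Gstm1 fell by 1.49 (adjusted p = 7.20e-10), the sulfotransferases Sult1c2 and Sult1a1 fell by 1.51 (adjusted p = 7.52e-08) and fell by 1.64 (adjusted p = 3.05e-07) on the log2 scale of the authors' deposited table. Sult1c2 averaged 994 ± 41.9 normalized reads in control (SD, n = 3) and 348 ± 188 in AOM+DSS (n = 3). Of 21 genes of mitochondrial respiration and butyrate oxidation, 2 fell and 1 rose: the acyl-CoA dehydrogenase Acads (log2 -0.74, adjusted p = 0.0394) and the monocarboxylate transporter Slc16a1 (log2 -0.55, adjusted p = 0.0455) fell in the authors' deposited table; 4 fell and 1 rose when adjusted over the list alone, and 9 fell at an unadjusted p under 0.05 (Fisher's exact test of lower calls, adjusted p = 0.665). Limma called 6 of them lower and 1 higher, and 12 lower and 2 higher without control library b and AOM+DSS library c. Camera ranked the list lower at the preset correlation (adjusted p = 9.84e-05; adjusted p = 0.570 with an estimated correlation). Of 16 genes of hypoxia and glycolysis, Hk2 (log2 1.32, adjusted p = 0.000104), the carbonic anhydrase Car9 (log2 0.71, adjusted p = 0.0165) and the peptide hormone Adm (log2 1.85, adjusted p = 0.0209) rose in the authors' deposited table, likewise 3 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.302). Of 21 transport genes, Fabp6, the ileal bile acid-binding protein (log2 -1.63, adjusted p = 0.00521), and Scnn1a (log2 -0.76, adjusted p = 0.0187) fell and Scnn1g rose in the authors' deposited table; 4 fell and 3 rose when adjusted over the list alone. Of 14 genes of histone acetylation, Hdac11 (log2 -1.33, adjusted p = 1.45e-06) and Hdac5 (control mean 2.07 times the AOM+DSS mean, adjusted p = 0.000172) fell in the authors' deposited table, likewise 2 when adjusted over the list alone. Of 16 p53 targets, Rprm (log2 -2.91, adjusted p = 0.000368) and Gdf15 (log2 -1.08, adjusted p = 0.0226) fell and Phlda3, an Akt inhibitor, rose (log2 2.73, adjusted p = 0.0245) in the authors' deposited table; 2 fell and 2 rose when adjusted over the list alone. DESeq called 0 of 21 DNA methylation and Polycomb genes (2 at an unadjusted p under 0.05; limma 0, but 4 higher and 2 lower without control library b and AOM+DSS library c; 0 when adjusted over the list alone), with Dnmt1 at a log2 fold of -0.02 and Tet3, which oxidizes methylcytosine, at 0.13 in the authors' deposited table. Herpud1 was the one of 16 genes of the unfolded protein response that rose (log2 0.60, adjusted p = 0.0446 in the authors' deposited table), and none did when adjusted over the list alone.

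Limma called 3155 of 18309 genes, but 531 without control library a, 691 without control library c, 716 without AOM+DSS library a and 1436 without AOM+DSS library b. Without control library b and AOM+DSS library c together it called 6694. It called 63 of 71 named genes tested, and not Capn9, Creb3l1, Insl5, Rgs13 (above), Gdf15 (log2 -1.16, adjusted p = 0.0585), Gzmb (log2 3.62, adjusted p = 0.0760), Pdgfrb (log2 -1.58, adjusted p = 0.0598) and Slc16a1 (log2 -0.60, adjusted p = 0.103). Of the 63, 28 lost the call without control library a, 28 without control library c, 27 without AOM+DSS library a, 13 without AOM+DSS library b, and up to 5 without either of the others, and Cd74 and H2-Eb1 were among those lost.

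Both comparisons shared many calls. Of 17819 genes tested in both, 645 were called in both in the authors' deposited table, 398 higher in both, 246 lower in both and 1, Pdlim4, in opposite directions. Pdlim4 was singled out after its values were seen. Independent lists of these sizes would share 26.6 higher and 11.1 lower genes. Lists as long as these, ranked in unchanged groups simulated against the same controls, shared 162.2 higher (133 to 188 over 200 simulations) and 89.4 lower genes (69 to 113). The 644 genes shared in the same direction made up 81.1% of the DSS calls tested in both. A further 149 genes were called in DSS alone and 975 in AOM+DSS alone. Across 10640 genes with a mean of at least 100, which are not independent replicates, the log2 fold changes of the authors' deposited table correlated with Pearson's r of 0.868 and Spearman's rho of 0.791. Unchanged groups simulated against the same controls gave an r of 0.530 (0.470 to 0.582 over 200 simulations), and the covariance was 0.385 against a simulated 0.037. These simulations share the controls but draw each gene independently. As the 3 controls could not be split with at least 2 on each side, part of the excess may still come from the shared controls.

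The 2 treated groups were compared directly with limma on the recovered reads, a test added after the data were seen. The Wnt antagonists Notum and Dkk2 were higher in AOM+DSS than in DSS, and the B lineage factor Pax5 was lower. The call of Pax5 was lost without AOM+DSS library a (below). Limma called 367 of 16284 genes, 354 higher and 13 lower in AOM+DSS, a balance that shifts without DSS libraries a and b (below). Of 1747 genes called in at least one comparison with control and compared by group means of the authors' deposited table, 421 differed at least 2-fold, 380 higher and 41 lower in AOM+DSS. That balance depends in part on the choice of genes, as 975 were called in AOM+DSS alone and 149 in DSS alone (above). The 6 highest differences belonged to Dkk2, Notum, Thbs2, Tbx3, Mgp and Cdh13. Notum stood at 3.03 ± 2.75 normalized reads in DSS (SD, n = 4) and 1812 ± 1073 in AOM+DSS (n = 3), with a log2 difference of 8.96 on the log2(value + 1) scale (limma, adjusted p = 0.000898). On the same scale the differences were 7.80 for Dkk2 (limma adjusted p = 0.00175), 7.80 for Thbs2, a matrix glycoprotein (adjusted p = 0.000968), 7.94 for the transcription factor Tbx3 (adjusted p = 0.000898), 7.81 for the matrix Gla protein Mgp (adjusted p = 0.00174) and 6.43 for the cadherin Cdh13 (adjusted p = 0.00669). Thbs2, Mgp and Cdh13 are also made by stromal cells, and recovered fibroblast and matrix markers summed to 7017 to 9420 normalized reads in AOM+DSS against 1004 to 2382 in DSS.

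The 6 lowest differences belonged to Pax5, Haao, Tppp3, Acap1, Spib and Mptx1. Pax5 stood at 229 ± 46.8 normalized reads in DSS (SD, n = 4) and 26.7 ± 20.3 in AOM+DSS (n = 3). It was lower in AOM+DSS by limma (log2 -3.47, adjusted p = 0.0269). Haao, an enzyme of tryptophan breakdown (log2 -2.56, adjusted p = 0.0269), and Acap1 (log2 -1.85, adjusted p = 0.0311) were lower by limma, while Tppp3 (log2 -2.41) and Spib, a transcription factor of B and M cells (log2 -1.97, adjusted p = 0.111), did not pass. Mptx1 was not tested, as its DSS reads were not recovered. Camera with a preset correlation ranked Wnt targets higher in AOM+DSS (adjusted p = 2.34e-18; adjusted p = 0.296 with an estimated correlation), Paneth cell genes higher (adjusted p = 3.60e-08; adjusted p = 0.267 with an estimated correlation), fibroblast and matrix markers higher (adjusted p = 4.75e-07; adjusted p = 0.296 with an estimated correlation) and B and plasma cell markers lower (adjusted p = 1.47e-08; adjusted p = 0.387 with an estimated correlation). The B and plasma cell sum was 378 to 1265 normalized reads in AOM+DSS, against 2462 to 12006 in DSS.

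The direct test rested on single libraries: limma called 74 genes without AOM+DSS library a, 85 without AOM+DSS library b, 597 without AOM+DSS library c, and 196, 187 and 197 without DSS libraries b, c and d. Without DSS libraries c and d together it called 52, and without a and b together 1673, of which 1021 were higher and 652 lower in AOM+DSS. Called lower in AOM+DSS were 0 genes without AOM+DSS library a, 0 without DSS libraries c and d, and 1 without AOM+DSS library b. The lower calls of Pax5, Haao and Acap1 were thus lost without AOM+DSS library a and without DSS libraries c and d.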

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

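All tests in this part other than the single-library comparisons were chosen after the result was seen.

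Among 85 named genes tested in the 4 DSS libraries, 9 had a library far from the others (gap over range above the 95% value of Dixon's test). For independent genes with normally distributed values, chance gives about 1 in 20. The values were normalized reads rather than logs and several of these genes moved together, so the count of 9 is not a test against chance. DSS library b stood highest for S100a9 (2739.6 normalized reads, others up to 335.1), Cxcl2 (1914.8, others 36.8 to 286.1), S100a8 (1296.0, others 29.7 to 199.2), Clec4e (630.3, others 6.2 to 89.3), Clec4d (313.1, others 3.1 to 41.1) and Sult1c2 (583.3, others 429.2 to 446.1). DSS library a stood highest for Cd79a (2485.9, others 395.5 to 746.5). DSS library d stood highest for Cxcl5 (294.7, others 105.1 to 135.9) and lowest for Thbs2 (0.0, others 1.4 to 1.6), a difference of 1 or 2 reads that says little.

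Over 35 genes of the myeloid and cytokine lists, DSS libraries a and b, the deeper ones, exceeded c and d by a median log2 ratio of 1.51, and 29 genes were higher in both. Thinning all 4 libraries to one depth left a median of 1.388. Thinning keeps the expected normalized value of each gene, so it cannot decide whether depth plays a part. A correction for GC content and length left 1.557, against 1.447 for the same genes uncorrected, so that bias does not account for the whole difference. A larger admixture of immune cells is a candidate explanation: B and plasma cell markers had a median log2 ratio of 1.724, with all 9 tested higher in both a and b, while interferon-stimulated genes stood at -0.21. T and NK cell markers had a ratio of 1.76, but only 7 of 14 were higher in both, and their sum was 5536 normalized reads in a against 1067, 779 and 1041 in b, c and d. Of markers that are not immune, endothelial ones had a ratio of 1.62 (5 of 7 higher in both), fibroblast ones 0.77 (4 of 11) and smooth muscle ones 0.19 (1 of 5), so immune cells alone need not be the source. Antimicrobial and acute phase genes had a ratio of 0.26, with 5 of 11 higher in both a and b. More severe inflammation in those samples was not tested and stays open.

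MHC class II transcripts were higher in both treated groups, with medians of 2.57 in DSS and 2.42 in AOM+DSS. In AOM+DSS, admixed B cells as the whole source are argued against, as 9 reported B and plasma cell markers had a median of 0.599, far under that of class II, and one of 0.95 by limma, where class II had 3.25. One of them, the plasma cell transcript Igj, did not pass but stood above class II by limma (log2 3.97, adjusted p = 0.113; 1.68 in the authors' deposited table), so a test on the highest marker alone would leave admixed B cells open by limma. A bias of GC content or length is argued against as well, as 103.0% of the AOM+DSS change was left after correction. In DSS, class II from admixed B cells (median of the reported markers 3.034) or myeloid cells (median 1.539) cannot be told apart from class II made by the epithelium, because only part of the markers reached the class II median, and the same holds for myeloid cells in AOM+DSS (median 3.012). Expression by epithelial cells may be a further source and was not tested.

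Other splits of the libraries into groups of the same sizes were counted with limma. For DSS against control, 1 of 35 splits, the real one with 876 calls, gave as many, and the highest other gave 0. This argues against chance alone but cannot exclude it, as 35 splits allow no share below 1 of 35. For AOM+DSS against DSS, 1 of 35, the real one with 367, gave as many, but a split into both deepest DSS with both deepest AOM+DSS libraries against the rest gave 344, nearly the real count. These libraries are thus also divided along a line that follows depth, in part cell content and, in DSS, GC content and gene length, and these were not separated for this split. The real comparison gave 359 calls after correction for GC content and length, against 334 for the same genes uncorrected. For AOM+DSS against control, the real split gave 3155 calls and the highest other 0, and 10 splits, of which 1 gave as many, are too few for a share under 0.05.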

How the results depend on the processing

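The limma results, the correction for GC content and the left-out pairs of libraries in this part were chosen after the data were seen. From the authors' p-values, 462 DSS and 981 AOM+DSS genes passed at an adjusted p of 0.01 and 219 and 387 by Bonferroni, where a stricter rule passes fewer by construction. Other filters and thresholds moved neither count by over 1.5 times. Limma called 876 genes in DSS. Of the authors' 794 DSS calls it tested 644 and called 523. In AOM+DSS it called 3155 genes, and of the authors' 1630 calls there it tested 1622 and called 1512. The cause of the larger limma count in AOM+DSS was not tested. Leaving out 1 library gave 147 (without control library a) to 1022 calls in DSS, 531 (without control library a) to 4366 in AOM+DSS and 74 (without AOM+DSS library a) to 597 (without AOM+DSS library c) between the treatments. Other libraries that moved a count by over 1.5 times were control library c (150 in DSS, 691 in AOM+DSS), DSS library d (501), AOM+DSS libraries a (716) and b (1436), and, between the treatments, AOM+DSS library b (85) and DSS libraries b (196), c (187) and d (197). Left-out pairs gave 1516 (without DSS libraries a and b) and 1846 (without c and d) in DSS, 6694 in AOM+DSS (without control library b and AOM+DSS library c), and 1673 (without DSS libraries a and b) and 52 (without c and d) between the treatments. The overlap fell from 645 to 382 genes at an adjusted p of 0.01, and the correlation was 0.765 at a mean of at least 10 and 0.706 over genes called in neither. Camera with an estimated correlation called 0 lists in DSS, 0 in AOM+DSS and 0 between the treatments, against 12, 13 and 13 with the preset one. No named gene reversed. In DSS, 45 of 52 named results kept their side of the threshold with limma, 6 lost it and 1 gained it; in AOM+DSS, 71 of 79 kept it and 8 lost it. With other pseudocounts all 78 and 85 kept theirs. The same 7 and 10 lists passed Fisher's exact test at an adjusted p of 0.1 and over members with a mean of at least 10. Not run were the alternatives for count tables (another normalization, another tool, no count filter), as no counts per sample were used. No paired analysis was possible because the columns carry no replicate number. Reads of highly expressed genes were not recovered in DSS, so limma says nothing of them there.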

Other observations

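The genes in this part were chosen after their values were seen, and all its tests were chosen after the result was seen.

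Genes of the circadian clock changed in both comparisons in the authors' deposited table. Of 15 clock genes, 9 were called in both, 5 lower and 4 higher. The output factors Dbp (log2 -5.51 in DSS, -4.37 in AOM+DSS), Tef (-3.02, -2.34) and the repressors Per3 (-2.03, -1.93), Nr1d1 (-2.56, -1.89) and Nr1d2 (-1.80, -0.98) were lower in the authors' deposited table. Arntl, which encodes the activator BMAL1 (log2 1.45, 0.86), its partner Npas2 (1.08, 0.86), the repressor Cry1 (2.03 in DSS) and Nfil3 (1.34, 1.53) were higher in the authors' deposited table. Nr1d1 averaged 4622 ± 649 normalized reads in control (SD, n = 3), 784 ± 398 in DSS (n = 4) and 1244 ± 208 in AOM+DSS (n = 3).

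Some genes of other kinds changed far. Khdc1a stood at 34.4 ± 11.4 normalized reads in control (SD, n = 3), 1653 ± 275 in DSS (n = 4) and 1195 ± 319 in AOM+DSS (n = 3), with Khdc1c, of the same family, at 6.06 ± 2.82, 259 ± 35.9 and 194 ± 67.3. Strc, which encodes stereocilin of the inner ear, was higher by 4.57 in DSS and 4.23 in AOM+DSS on the log2 scale of the authors' deposited table. Wfdc18 had the lowest adjusted p of the AOM+DSS comparison in the authors' deposited table (log2 4.67, adjusted p = 7.51e-68) and rose in DSS too (log2 3.27, adjusted p = 2.06e-37). Bex1 was lower in DSS (log2 -3.87) and had a log2 fold of 0.73 in AOM+DSS (adjusted p = 0.859) in the authors' deposited table; by limma it was higher in AOM+DSS than in DSS (log2 4.21, adjusted p = 0.0160).

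For the clock genes, a bias of GC content or gene length is argued against, as 100.6% of the log2 change was left after correction (the lower of the medians of both comparisons) and all 9 genes were still called. In DSS, a lower share of epithelial cells is argued against too, as the pan-epithelial list had a median log2 fold of 0.11. None of its members lay below -0.42, against a median of -2.56 for the falling clock genes. The same was not tested in AOM+DSS, where the pan-epithelial median was 0.023. A different time of day at collection may account for the 9 genes, since genes of opposite phase moved in opposite directions, but no collection time is given in the labels, so it cannot be told apart from an effect of the treatments on the clock.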
